A study of Arabidopsis thaliana with 12 samples.

How the data were processed

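The series holds 12 one-colour Agilent arrays in 4 groups of 3: 14-day-old Arabidopsis Col-0 control seedlings, callus-like plants that express WIND1 from the constitutive 35S promoter without further treatment, callus of the T87 cell line on medium with 500 nM NAA, and callus induced and kept with 500 µg/L 2,4-D. NAA and 2,4-D are synthetic auxins. Per the labels, plants and calli grew on solid MS medium, total RNA was labelled with Cy3, and each array is a biological replicate from a different plant or a different callus. Groups and replicate numbers were taken from the sample titles.

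Per the file headers, the deposited scanner files hold spot intensity on a linear scale from Agilent Feature Extraction, and per the submitters' processing notes its version was 9.1.3.1. The column used is the processed signal, from which the scanner software had subtracted the background. Each array has 39102 spots, of which 1417 are controls. The 37685 other spots belong to 37478 probes, 23 of which are spotted 10 times. No spot was saturated on any array. The authors' deposited series table is on a natural log scale, and its transformation was worked out by setting each column against the scanner values: it is the natural log of the processed signal minus 1 constant per group, with no scaling of single arrays and no stated direction. Its column medians were -1.74, -2.08 and -1.81 for the seedlings, -1.93, -1.56 and -2.02 for 35S:WIND1 callus, -2.52, -2.40 and -2.57 for T87 callus, and -2.49, -2.70 and -2.34 for 2,4-D-induced callus. Why 1 constant was used per group stays unknown, so this table served only as an alternative. A genome build is not given in the sources used here, and no coordinate is printed. Probes were named through the locus codes in the scanner files: 26236 probes carry a code of 25665 loci. A reference table of assembly TAIR10.1 listed 25449 of these loci, of which 10189 have a gene symbol, and a list member with another symbol there keeps the name of its list. The array's annotation can be old, 8812 probes are named by a genomic position and 2430 others have no locus code. The columns of all samples were mapped.

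Computed here were the log2 processed signals minus each array's 75th percentile over non-control spots. That percentile lay between 1755 and 3716 units, the median signal between 123 and 255 units, and 57.1% to 65.9% of spots were well above background. Control spots and the 25 to 218 outlier spots per array were removed, and spots of a probe were averaged. A probe entered the tests if it was well above background on all 3 arrays of at least 1 group, and the brightest probe stood for a gene. This left 21847 probes of 21325 genes. Of the genes tested, 461 had several such probes, and among the 445 of these with several probes measured on all 12 arrays, 1 to 5 genes per comparison had probes called in opposite directions. The number of arrays limits the precision of every value.

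Each comparison was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with all 12 arrays in 1 fit and no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Where a gene was not well above background on any array of the dimmer group, the text gives "at least N-fold": the mean of the brighter group over a floor, which on each array of the dimmer group is the higher of the lowest signal well above background and the gene's own signal. Where only some arrays of a group measured a gene, their number is given, and the fold rests in part on signals not well above background. Standard errors (SE) are those of log2 changes.

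Tests of 26 gene lists with 472 members, 455 of them measured, used camera with a preset correlation of 0.01 between genes, adjusted over 156 tests (26 lists in 6 comparisons). The lists cover pathways, regulators, stress and hormone responses, housekeeping genes and markers of tissues, and the results give each under its name. No gene is in more than 1 list. Groups, tests, thresholds, lists and the rule for named genes were fixed before the data were examined. By that rule the text names WIND1, and per comparison the 5 largest rises and 5 largest falls among called genes that have a symbol, arrays that do not overlap and signals well above background on all arrays of both groups. It also names up to 3 called members with the largest rise and 3 with the largest fall per list, and the 5 genes per direction with the largest smallest-of-3 change among genes shared by the calli or set apart in 1 callus. For length the text gives only part of these genes, picked after their values were seen, so larger changes can be left out.

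Main results were recomputed with normexp background correction (offset 50), quantile normalization, array median scaling, the deposited series values and no filter on dim probes. Further settings were the replicate or slide as a block and leaving out each array. Without list tests came a filter on all 12 arrays, the mean of a gene's probes and only the 6 arrays compared. So did eBayes with trend and robust, and other thresholds. List tests were repeated with an estimated correlation. The scanner files held no mean signal column, so normexp used the median signal and the median local background. Single spots had local backgrounds of up to 65208.5 units, against array medians of 53.0 to 58.0 units. Another alternative, chosen after seeing the data, therefore set local backgrounds over 2 times the array median to that median. Each of the 3 slides held 1 array of every group, always at the same position, so position on the slide and group cannot be told apart. Slide and replicate number coincide, so these blocks are the same. Shared seedling arrays were simulated in 20 data sets with unchanged groups.

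The code was tested on simulated data for 35S:WIND1 callus against the seedlings over 21325 genes. Noise was drawn for each gene independently, with its moderated spread shared by the 4 groups. Neither the wider spread of 35S:WIND1 callus nor correlation within lists was simulated, so correlated lists stay untested. Of genes changed 3-fold 76 of 100 were recovered, and of genes changed 6-fold 94 of 100, none in the wrong direction. There 14 of 21095 unchanged genes were called, a planted list of 30 genes had an adjusted p of 3.25e-37, and 0 of 25 unchanged lists passed. Data handling used the R package data.table, version 1.17.8, and figures used Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.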

Results

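Transcript levels were measured on 12 one-colour arrays in 14-day-old Arabidopsis seedlings and in 3 kinds of callus. These were callus formed by plants that express WIND1 from the constitutive 35S promoter, callus of the T87 cell line, which was kept with the auxin NAA, and callus induced with the auxin 2,4-D. Each group had 3 arrays (n = 3). WIND1 is an AP2/ERF transcription factor named for wound-induced dedifferentiation, and the design asks how callus formed through it compares with calli kept on auxin. No array was a copy of another. Values are log2 signals relative to the 75th percentile of the array, and 21325 genes were tested. Where a gene was not well above background in the dimmer group, its change is given as at least N-fold.

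Arrays of the same group resembled each other most among the seedlings, with correlations across genes of 0.986 to 0.991, and least in 35S:WIND1 callus, with 0.944 to 0.956. The ranges were 0.980 to 0.986 in T87 callus and 0.977 to 0.986 in 2,4-D-induced callus. Genes are not independent replicates in such correlations. The median SD of a gene was 0.11 in seedlings, 0.36 in 35S:WIND1 callus, 0.18 in T87 callus and 0.20 in 2,4-D-induced callus. Seedling arrays correlated with single arrays of other groups at a mean of 0.819 for 35S:WIND1 callus, 0.717 for 2,4-D-induced callus and 0.662 for T87 callus (9 pairs each). Between calli the means were 0.820 for 35S:WIND1 and 2,4-D-induced callus, 0.781 for T87 and 2,4-D-induced callus, and 0.779 for 35S:WIND1 and T87 callus. Position on the slide and group cannot be told apart.

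**Figure D1:**
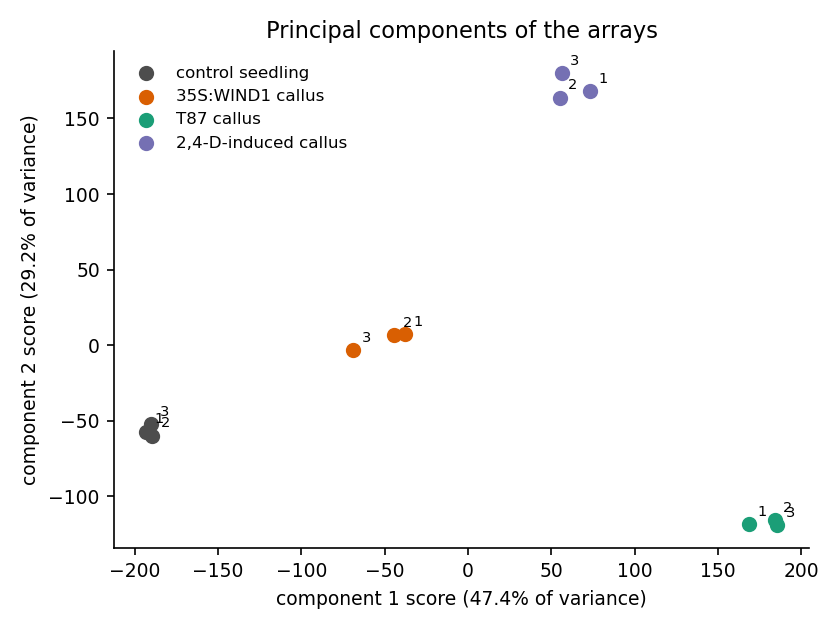
Scores of the 12 arrays on the leading pair of principal components, which hold 47.4% and 29.2% of the variance, with points for arrays, coloured by group and numbered by replicate. The 3 arrays of each group lie together, and those of 35S:WIND1 callus are the most spread.

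The WIND1 transcript (AT1G78080) was highest in 35S:WIND1 callus, at a mean log2 level of 3.58 ± 0.35 (SD, n = 3). The levels were 1.26 ± 0.09 in seedlings, 2.27 ± 0.29 in T87 callus and 2.86 ± 0.25 in 2,4-D-induced callus. WIND1 was 4.97-fold higher in 35S:WIND1 callus than in seedlings (log2 change 2.31, SE 0.21, adjusted p = 1.52e-05), with changes of 2.70, 1.83 and 2.41 on the 3 slides. It was also called higher than in seedlings in 2,4-D-induced callus, by 3.04-fold (adjusted p = 8.5e-05), with 1.95, 1.37 and 1.48 on the slides. In T87 callus it was 2.01-fold higher (adjusted p = 0.00165), with 1.305, 0.58 and 1.14. The level in 35S:WIND1 callus exceeded that in T87 callus 2.47-fold (adjusted p = 0.000431), with 1.40, 1.26 and 1.26. It was 1.64-fold that in 2,4-D-induced callus, which was not called (adjusted p = 0.0178), with 0.75, 0.46 and 0.92. The difference of -0.59 between T87 and 2,4-D-induced callus was not called either (adjusted p = 0.0316), with -0.65, -0.79 and -0.34. The call in T87 callus ended with quantile normalization (log2 change 0.97), with the deposited series values (0.98) and without T87 replicate 1 (0.89) or 3 (0.96) or seedling replicate 1 (0.98) or 3 (0.99). For 35S:WIND1 over T87 callus it ended with median scaling (0.86), and 35S:WIND1 over 2,4-D-induced callus was called with the deposited values (1.37). Whether the single WIND1 probe lies in the part of the transcript that the transgene carries is not given in the sources used here.

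**Figure D2:**
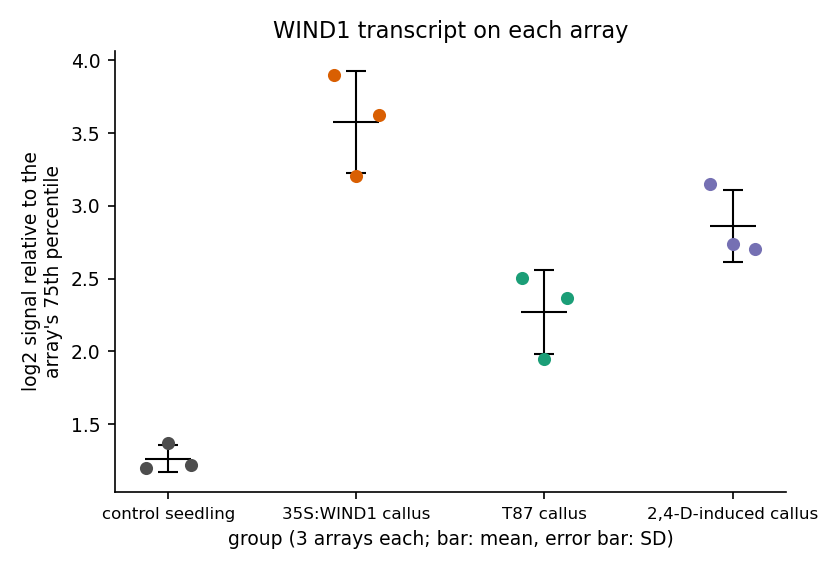
Log2 signal of the WIND1 probe relative to the 75th percentile of each array (vertical axis) in the 4 groups, where points are arrays, bars are means and error bars are SDs of 3 arrays. Means are 1.26 in seedlings and 3.58 in 35S:WIND1 callus.

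All counts of called genes are relative to each array's 75th percentile, and other scalings moved the centre. The median log2 change of all genes was 0.07 for 35S:WIND1 callus, -0.0033 for T87 callus and 0.15 for 2,4-D-induced callus against the seedlings. It was -0.0029, -0.07 and -0.05 for 35S:WIND1 over T87, 35S:WIND1 over 2,4-D-induced and T87 over 2,4-D-induced callus. In this order it became 0.50, 0.86, 0.90, -0.44, -0.39 and 0.08 with median scaling and 0.56, -0.03, -0.02, 0.51, 0.58 and 0.10 with the deposited series values. Quantile normalization gave 0.15, 0.15, 0.29, -0.07, -0.11 and -0.0039, and normexp gave -0.11 for T87 callus against the seedlings. Of the 76 list tests past the threshold, 75 had medians of the same sign on all 3 slides. With the slide as a block all 76 stayed past it and 1 more passed. With a correlation between genes estimated from the data, 0 of the 156 list tests passed.

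**Figure D3:**
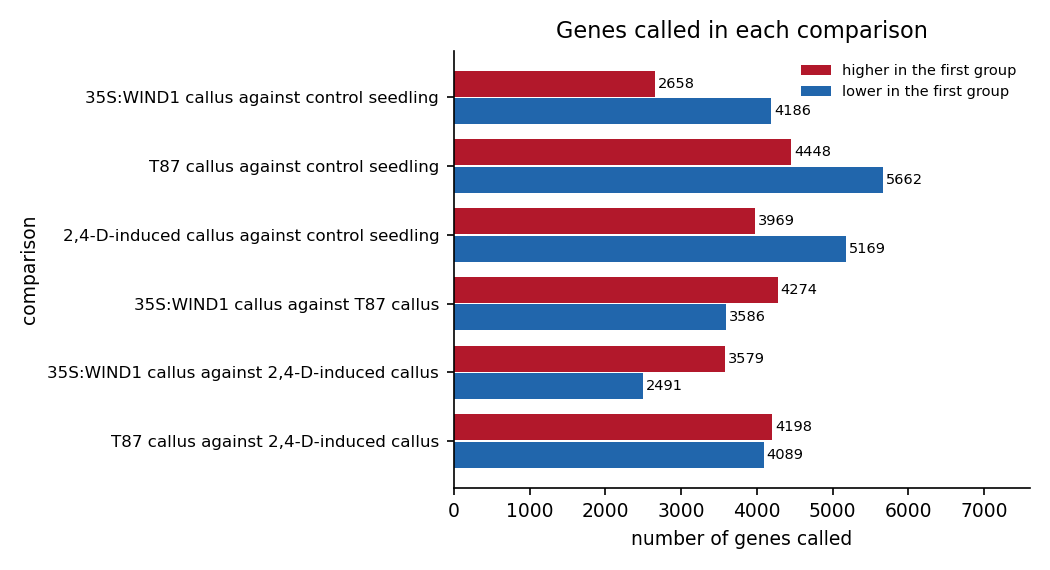
Number of genes called (adjusted p under 0.05 and at least 2-fold, horizontal axis) in each comparison, with red bars for genes higher and blue bars for genes lower in the first group named. The totals run from 6070 to 10110 genes.

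In callus of plants that express WIND1, the stem cell genes WUS and CLV3 rose against the seedlings and all 51 measured photosynthesis genes fell (adjusted p = 3.63e-16, or adjusted p = 0.478 with an estimated correlation). WUS, the homeodomain factor of the shoot stem cell niche, rose by at least 113-fold (adjusted p = 2.62e-06) and CLV3, its peptide signal, by at least 201-fold (adjusted p = 3.61e-06), both from signals not well above background. Among genes with a symbol measured on every array of both groups, the largest rises were in LTP4 (AT5G59310), a lipid transfer protein gene, by 360.4-fold (SE 1.45, adjusted p = 0.000808), and in JRG21 (AT3G55970), which encodes a dioxygenase that hydroxylates jasmonic acid, by 254-fold (SE 0.68, adjusted p = 1.05e-05). The defensin gene PDF1.4 (AT1G19610) rose 131-fold (SE 0.60, adjusted p = 1.03e-05). The largest falls among genes so measured were in CA1 (AT3G01500), the chloroplast carbonic anhydrase, by 293-fold (SE 0.59, adjusted p = 3.64e-06), and the myrosinase gene TGG2 by 249-fold (SE 1.18).

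The photosynthesis genes had a median log2 change of -2.65, with -2.76, -2.85 and -2.16 on the slides. The Rubisco genes RBCS2B and RBCS1B fell 99.95-fold and 50.6-fold, though near-identical copies may share signal on such probes. Chlorophyll synthesis genes fell in 16 of 18 cases (median -2.23, adjusted p = 1.69e-08). GLK1, a regulator of chloroplast development, fell 40.2-fold, and the list had adjusted p = 0.432 with an estimated correlation. Among 32 regeneration and callus regulators 16 rose and 5 fell (median 1.23, or 0.88 with genes at their bound, adjusted p = 0.00795, or adjusted p = 0.292 with an estimated correlation, and median 0.76 without 35S:WIND1 replicate 1). Beside WUS, the shoot regeneration factor ESR1 rose 211-fold (2 of 3 seedling arrays measured it) and the boundary gene CUC1 69.5-fold, while the root stem cell factor PLT2 fell at least 6.42-fold. The auxin response list had 4 higher and 11 lower of 21 (median -1.05, adjusted p = 0.00687, or adjusted p = 0.432 with an estimated correlation). The Aux/IAA repressor genes IAA17 and IAA3 fell 83.1-fold and 43.0-fold, and the auxin-conjugating GH3.5 rose 5.53-fold. For cytokinin response 1 rose and 12 fell of 16 (median -2.29, or -2.22 at bounds, adjusted p = 0.00431, or adjusted p = 0.518 with an estimated correlation). The response regulator ARR6 fell 19.5-fold.

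Of 17 DNA replication genes 3 fell, among them the origin-licensing gene CDC6 by 2.93-fold (median -0.62, adjusted p = 0.026, or adjusted p = 0.698 with an estimated correlation). Without 35S:WIND1 replicate 3 the list no longer passed (-0.38, adjusted p = 0.199). Heat shock genes rose in 7 of 10 cases (median 1.45, adjusted p = 0.00221), HSP17.6A by 10.8-fold, with adjusted p = 0.478 with an estimated correlation. Flavonoid synthesis fell in 5 of 15 (median -1.45, adjusted p = 0.00221, and -0.75 without 35S:WIND1 replicate 1). Chalcone synthase, TT4, fell 42.9-fold, and the list had adjusted p = 0.499 with an estimated correlation. Glucosinolate genes, which include TGG2, fell in 8 of 16 (median -1.98, adjusted p = 0.00533, or adjusted p = 0.478 with an estimated correlation). Of 10 stomata and trichome markers 2 rose and 8 fell (median -4.46, adjusted p = 0.0222, or adjusted p = 0.55 with an estimated correlation). The stomatal patterning receptor gene TMM fell 25.4-fold, and ERL1, which encodes a receptor kinase of the same pathway, rose 8.87-fold.

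The other 16 lists did not pass (adjusted p in parentheses), although single members were called. Of 15 xylem and secondary wall markers 3 rose and 0 fell (0.445), the vessel regulator VND7 by 16.9-fold, and of 6 phloem markers 2 fell (0.212). In epidermis and cuticle 1 rose and 4 fell of 12 (0.105): LTP2 rose 46.8-fold and PDF1 fell 7.27-fold. Root markers had 4 higher and 7 lower of 18 (0.0772), with the Casparian strip gene CASP1 down 79.1-fold. Leaf polarity and meristem markers had 4 higher and 8 lower of 13 (0.113). In jasmonate and wounding 11 rose and 6 fell of 23 (0.104), among the former the wound-induced ribonuclease gene RNS1 by 38.3-fold. Defence had 6 higher and 1 lower of 16 (0.444). Hypoxia had 7 and 1 of 12 (0.108). Higher and lower counts were 3 and 0 of 13 for senescence (0.444), 2 and 0 of 13 for the seed programme (0.531), and 5 and 1 of 13 for the clock (0.308). They were 1 and 1 of 24 for mitosis (0.261), 2 and 4 of 17 for D-type cyclins and CDK inhibitors (0.682) and 0 and 0 of 19 for the ribosome (0.906). Polycomb and DNA methylation had 2 and 1 of 23 (0.14) and housekeeping genes 0 and 0 of 12 (0.663). Some passed in other settings, given with their median and adjusted p. Root markers passed with normexp (-0.48, 0.045), median scaling (-0.05, 0.0222), the deposited values (0.0089, 0.0375) and without 35S:WIND1 replicate 3 (-0.67, 0.0389). Leaf polarity passed with median scaling (-1.09, 0.0191) and the deposited values (-1.03, 0.0198), epidermis with median scaling (-0.40, 0.033) and jasmonate without a filter on dim probes (1.03, 0.0488). Hypoxia passed with normexp (0.97, 0.0492) and without 35S:WIND1 replicate 1 (1.85, 0.00876), mitosis without 35S:WIND1 replicate 1 (-0.68, 0.0389) and phloem without 35S:WIND1 replicate 2 (-1.50, 0.0492). Adjusted over the list alone, the counts differed from these only for defence (5 higher, 1 lower) and xylem (2 higher).

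With limma, 2658 genes were higher and 4186 lower in 35S:WIND1 callus than in seedlings, 32.1% of those tested. Arrays did not overlap for 6708 of them, picked on the same arrays, and for 13421 of all 21325 genes (10% by chance). With the slide as a block 2645 were higher and 4175 lower, and 6726 of 6779 called genes with all values had the same direction on all 3 slides. Median scaling turned the split to 4954 higher and 3252 lower and the deposited values to 5444 and 3107. With normexp 2855 genes were called, 55 of the 119 gene changes chosen for naming ended or turned, and the heat shock (0.65, adjusted p = 0.0799) and stomata lists (-1.49, adjusted p = 0.143) no longer passed. DNA replication did not pass with the deposited values (-0.13, adjusted p = 0.123) and regeneration did not with median scaling (1.65, adjusted p = 0.0957).

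In T87 callus, the chloroplast heat shock gene HSP21 rose at least 497-fold against the seedlings (adjusted p = 1.31e-06) and LEC1, a regulator of embryo development, 91.6-fold (adjusted p = 1.8e-07). Among genes with a symbol measured on every array of both groups, the largest rises were in the nitrate transporter gene NRT2.6 (AT3G45060), by 566-fold (SE 1.19, adjusted p = 6.88e-05), the poly(A)-binding protein gene PAB5 (AT1G71770), by 252-fold (SE 0.33, adjusted p = 4.03e-08), and NRT2.5 (AT1G12940), another nitrate transporter gene, by 222-fold (SE 0.60, adjusted p = 1.96e-06). The largest falls among genes so measured were in RBCS2B (AT5G38420), a Rubisco small subunit, by 2071-fold (SE 0.81, adjusted p = 1.46e-06), and LHCB2.3 by 1479-fold. The Rubisco gene RBCS3B fell less, from a mean log2 level of 6.52 to 5.63. The glucosinolate enzyme gene CYP79F1 fell 742-fold (a log2 change of -9.54, or -6.35 as the mean of its probes) and CA1 730.1-fold.

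Heat shock genes rose in 9 of 10 cases, with a median of 5.63 (adjusted p = 9.33e-05) and 5.47, 5.70 and 5.80 on the slides. HSP17.6A rose 132-fold, and the list had adjusted p = 0.432 with an estimated correlation. The seed and embryo programme had 10 higher and 2 lower of 13 (median 3.399, or 2.74 at bounds, adjusted p = 0.0103, or adjusted p = 0.432 with an estimated correlation). The oleosin gene OLEO2 rose at least 42.2-fold and the dehydrin gene RAB18 fell 12.1-fold. DNA replication rose in 14 of 17 (median 1.87, adjusted p = 0.000126), with 1.54, 1.81 and 2.01 on the slides. The helicase genes MCM4 and MCM5 rose 17.61-fold and 12.7-fold, and the list had adjusted p = 0.55 with an estimated correlation. Mitosis genes rose in 7 of 24 (median 0.84, adjusted p = 0.026, or adjusted p = 0.744 with an estimated correlation), CYCB1;1 by 2.81 on the log2 scale and CDKB1;1 by 5.02-fold. This list did not pass without T87 replicate 2 (0.70, adjusted p = 0.0533) or with median scaling (1.71, adjusted p = 0.0675). In ribosome and nucleolus 3 of 19 rose (median 0.41, adjusted p = 0.0289), RPS6B by 3.29-fold, with adjusted p = 0.695 with an estimated correlation. Hypoxia genes rose in 8 of 12 (median 2.74, adjusted p = 0.00803, or adjusted p = 0.55 with an estimated correlation), among them the oxygen-sensing oxidase PCO1 by 34.7-fold and the alcohol dehydrogenase ADH1 by 25.4-fold.

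Photosynthesis fell in 48 of 51 (median -2.29, adjusted p = 1.38e-09, or adjusted p = 0.55 with an estimated correlation), with -2.02, -2.72 and -2.19 on the slides. Chlorophyll synthesis fell in 12 of 18 (median -1.67, adjusted p = 0.000238), GLK1 by 67.7-fold, with adjusted p = 0.499 with an estimated correlation. All 16 glucosinolate genes fell (median -8.88, or -7.73 at bounds, adjusted p = 8.1e-07, or adjusted p = 0.35 with an estimated correlation). TGG2 fell at least 2868-fold. Flavonoid synthesis fell in 12 of 15 (median -4.86, or -4.81 at bounds, adjusted p = 0.000371), TT4 by at least 565-fold, with adjusted p = 0.478 with an estimated correlation. All 12 epidermis and cuticle markers were lower (median -7.12, or -6.43 at bounds, adjusted p = 1.35e-05), with PDF1, a protodermal gene, down at least 514-fold and adjusted p = 0.432 with an estimated correlation. All 18 root markers fell (median -4.47, or -3.72 at bounds, adjusted p = 2.66e-06), the beta-glucosidase gene PYK10 by 216-fold, with adjusted p = 0.35 with an estimated correlation. Of 10 stomata and trichome markers 9 fell (median -4.77, or -2.99 at bounds, adjusted p = 0.00228), the guard cell factor FAMA by at least 71.4-fold, with adjusted p = 0.487 with an estimated correlation. Xylem markers fell in 12 of 15 (median -3.73, adjusted p = 0.00621, or adjusted p = 0.639 with an estimated correlation), the protease gene XCP2 by 73.8-fold. Phloem markers fell in 5 of 6 (median -5.56, adjusted p = 0.00749, or adjusted p = 0.478 with an estimated correlation), SEOR1 by at least 323-fold.

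Leaf polarity and meristem markers had 3 higher and 9 lower of 13 in T87 callus (median -3.49, adjusted p = 0.0127, or adjusted p = 0.432 with an estimated correlation), with FIL, a gene of the lower leaf side, down at least 64.2-fold. The auxin response list had 2 higher and 10 lower of 21 (median -0.98, adjusted p = 0.028, or adjusted p = 0.478 with an estimated correlation). IAA3 fell at least 348-fold and IAA7 125-fold, and IAA1 rose 5.10-fold. Defence had 2 higher and 11 lower of 16 (median -2.09, or -1.43 at bounds, adjusted p = 0.0295, or adjusted p = 0.598 with an estimated correlation). PR5 fell at least 61.8-fold and PAD4 26.1-fold, and WRKY53 rose 6.45-fold. The remaining lists did not pass (adjusted p in parentheses). Regeneration regulators had 14 higher and 9 lower of 32 (0.382). Cytokinin response had 3 and 6 of 16 (0.302), jasmonate 4 and 14 of 23 (0.223), and D-type cyclins and inhibitors 4 and 7 of 17 (0.538). Senescence had 5 and 2 of 13 (0.498) and the clock 4 and 3 of 13 (0.734). Polycomb and DNA methylation had 9 and 2 of 23 (0.0859), with the DNA demethylase gene ROS1 down at least 74.9-fold, and housekeeping 0 and 2 of 12 (0.771). With their median and adjusted p, Polycomb passed with normexp (0.73, 0.0274) and without a filter on dim probes (0.67, 0.0489), and jasmonate with median scaling (-0.73, 0.0352). Adjusted over the list alone, 5 cytokinin genes were lower, 9 hypoxia genes higher, 10 stomata and trichome markers lower and 13 xylem markers lower, and the other counts were the same.

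With limma, 4448 genes were higher and 5662 lower in T87 callus than in seedlings, 47.4% of those tested (10071 with no array overlap). With the slide as a block 4445 were higher and 5660 lower, and 9971 of 9992 called genes kept their direction on all 3 slides. Median scaling turned the split to 9629 higher and 3911 lower, and under it the seed (4.27, adjusted p = 0.168) and hypoxia lists (3.61, adjusted p = 0.0784) did not pass. With normexp 5143 genes were called and 34 of 132 named changes ended or turned. The seed (0.72, adjusted p = 0.404), auxin (-0.72, adjusted p = 0.0561), stomata (-1.59, adjusted p = 0.0817) and leaf polarity lists (-2.14, adjusted p = 0.0554) did not pass with normexp, nor the ribosome list with the deposited values (0.39, adjusted p = 0.0735).

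In callus induced with 2,4-D, the root niche gene WOX5 rose 49.96-fold against the seedlings, the embryo factor BBM 49.9-fold and the root stem cell factor PLT1 46.5-fold. Among genes with a symbol measured on every array of both groups, the largest rises were in CKX3 (AT5G56970), a cytokinin oxidase, by 830.5-fold (SE 0.60, adjusted p = 5.11e-07), and the cell wall enzyme gene XTH11 (AT3G48580) by 689.7-fold (SE 0.60, adjusted p = 6.52e-07). ARD3 (AT2G26400), which encodes a dioxygenase of the methionine cycle, rose 227-fold (SE 0.91). The largest falls among genes so measured were in GOX1 (AT3G14420), the photorespiratory glycolate oxidase, by 1235-fold (SE 0.57, adjusted p = 2.67e-07), RBCS3B by 985-fold (SE 0.53) and the glycine decarboxylase gene GDCH by 801-fold (SE 0.29).

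Of the 32 regeneration regulators 22 rose and 0 fell (median 3.31, or 3.08 at bounds, adjusted p = 2.37e-05, or adjusted p = 0.11 with an estimated correlation), with 3.62, 3.28 and 3.57 on the slides. Hypoxia genes rose in 12 of 12 (median 3.19, adjusted p = 0.00075, or adjusted p = 0.499 with an estimated correlation), ADH1 by 35.9-fold and the pyruvate decarboxylase PDC1 by 30.3-fold. All 51 photosynthesis genes fell (median -5.85, adjusted p = 6.99e-22), with -5.41, -5.81 and -6.58 on the slides. RBCS2B fell at least 13330-fold, and the list had adjusted p = 0.45 with an estimated correlation. All 18 chlorophyll synthesis genes fell (median -4.31, adjusted p = 3.29e-10, or adjusted p = 0.432 with an estimated correlation), GLK1 by at least 597-fold and GLK2 by 141-fold. Flavonoid synthesis had 1 higher and 13 lower of 15 (median -5.51, or -4.71 at bounds, adjusted p = 0.000149, or adjusted p = 0.478 with an estimated correlation). TT4 fell 389.9-fold (1 of 3 2,4-D arrays measured it) and the regulator MYB11 rose at least 12.2-fold. Glucosinolate genes had 1 higher and 14 lower of 16 (median -6.84, or -5.17 at bounds, adjusted p = 1.52e-05, or adjusted p = 0.432 with an estimated correlation). TGG1 fell at least 3098-fold and the regulator MYB51 rose 4.80-fold. Epidermis and cuticle had 2 higher and 9 lower of 12 (median -3.07, adjusted p = 0.00456, or adjusted p = 0.499 with an estimated correlation), PDF2 and PDF1 down 47.1-fold and 37.3-fold. Stomata and trichome markers had 1 higher and 9 lower of 10 (median -5.35, or -3.66 at bounds, adjusted p = 0.00192), FAMA down at least 62.8-fold, with adjusted p = 0.478 with an estimated correlation.

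Root markers had 2 higher and 13 lower of 18 in 2,4-D-induced callus (median -2.99, adjusted p = 0.000889, or adjusted p = 0.432 with an estimated correlation), with the root hair regulator RHD6 up 9.97-fold. Xylem markers fell in 14 of 15 (median -4.28, or -4.19 at bounds, adjusted p = 0.000334), XCP2 by 229.6-fold (2 of 3 arrays measured it), with adjusted p = 0.55 with an estimated correlation. Phloem markers fell in 4 of 6 (median -2.74, adjusted p = 0.0289, or adjusted p = 0.499 with an estimated correlation), PP2-A1 by 12.5-fold and the sucrose transporter SUC2 by 10.1-fold. Leaf polarity and meristem markers had 2 higher and 9 lower of 13 (median -2.47, adjusted p = 0.02), KNAT1 up 6.94-fold, with adjusted p = 0.432 with an estimated correlation. The remaining lists did not pass (adjusted p in parentheses). Auxin response had 13 higher and 5 lower of 21 (0.0892). Its early auxin genes GH3.2 and GH3.3 rose 109-fold and 105-fold, and SAUR15 fell at least 47.2-fold. Cytokinin response had 6 higher and 4 lower of 16 (0.538), and jasmonate 4 and 10 of 23 (0.193). Defence had 5 and 2 of 16 (0.483), heat shock 2 and 0 of 10 (0.3), and senescence 6 and 1 of 13 (0.191). The clock had 6 and 2 of 13 (0.24), the seed programme 2 and 4 of 13 (0.35), and Polycomb and DNA methylation 5 and 1 of 23 (0.0631). D-type cyclins had 1 and 5 of 17 (0.308), DNA replication 0 and 1 of 17 (0.615) and mitosis 1 and 0 of 24 (0.392). The ribosome had 0 and 0 of 19 (0.71) and housekeeping 0 and 1 of 12 (0.368). In other settings, given with median and adjusted p, auxin response passed with normexp (2.12, 0.00561), the deposited values (2.18, 0.00818) and bright local backgrounds replaced (2.32, 0.0483). Polycomb passed with normexp (0.38, 0.046), no filter on dim probes (0.78, 0.031) and without seedling replicate 1 (0.73, 0.0486) or 2,4-D replicate 1 (0.78, 0.0444), jasmonate with median scaling (-0.31, 0.0369) and senescence with the deposited values (1.44, 0.0384). Adjusted over the list alone, 14 auxin genes were higher and 11 jasmonate and 5 phloem genes lower, and the other counts were the same.

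With limma, 3969 genes were higher and 5169 lower in 2,4-D-induced callus than in seedlings, 42.9% of those tested (9088 with no array overlap). With the slide as a block 3963 were higher and 5171 lower, and 9002 of 9025 called genes kept their direction on all 3 slides. Median scaling turned the split to 9630 higher and 3797 lower. With normexp 4670 genes were called, 36 of 115 named changes ended or turned, and the stomata (-1.27, adjusted p = 0.119) and leaf polarity lists (-1.56, adjusted p = 0.154) did not pass.

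**Figure D4:**
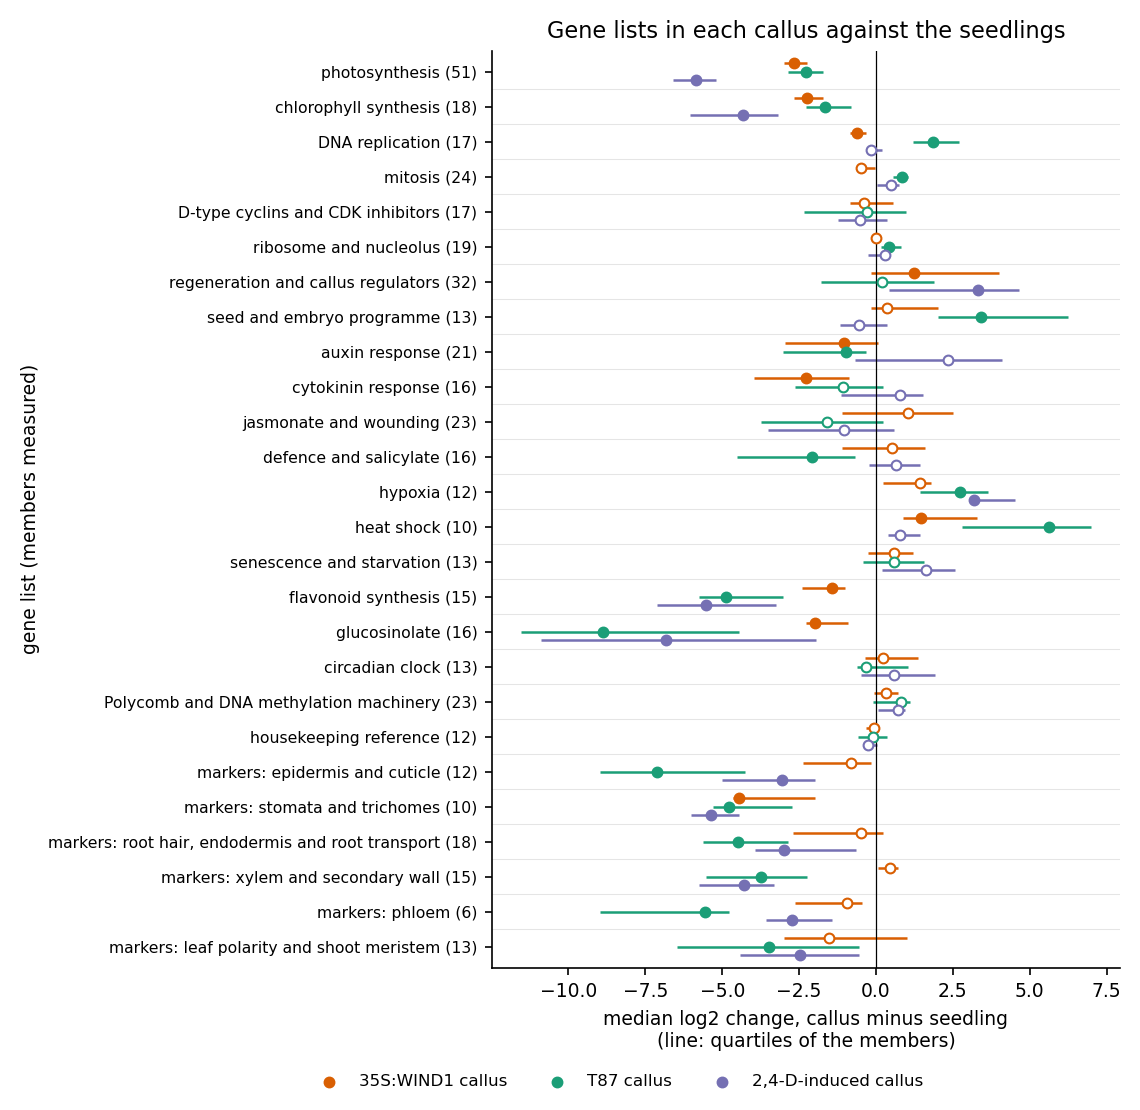
Median log2 change of each gene list (horizontal axis) in each callus against the seedlings, where filled dots passed the list test with a preset correlation, open dots did not, and lines span the quartiles of the members. The photosynthesis median is -2.65 in 35S:WIND1, -2.29 in T87 and -5.85 in 2,4-D-induced callus.

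Genes changed in all 3 calli against the seedlings included the cellulose synthase-like gene CSLG2 (AT4G24000), higher by at least 46.8-fold in 35S:WIND1, 36.4-fold in T87 and 49.3-fold in 2,4-D-induced callus. PDF1.4 was higher by 131-fold, 118-fold and 123-fold, and the endonuclease gene ENDO2 by 82.6-fold, 144-fold and 129-fold (2 of 3 seedling arrays measured it). XTH11 rose 77.7-fold, 95.5-fold and 689.7-fold. The auxin-responsive growth gene SAUR20 fell by at least 204-fold, 201-fold and 176-fold, and the methionine sulfoxide reductase gene MSRB6 by at least 249-fold, 245-fold and 215-fold. In all 915 genes were higher and 2436 lower in every callus, where independent lists of these sizes would share 103 and 269. In 20 simulated sets 0 were shared, but unchanged groups allow few calls, so this cannot decide.

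Of pairs, 35S:WIND1 and T87 callus shared 1390 higher and 3037 lower genes (554 and 1111 if independent), and 35S:WIND1 and 2,4-D-induced callus 1449 and 3171 (495 and 1015). T87 and 2,4-D-induced callus shared 1778 and 3581 (828 and 1372), and simulated sets, again with few calls, 0, 0 and 0.1 per pair. Fold changes correlated across genes at r = 0.598, 0.632 and 0.618 for these pairs (rho 0.544, 0.610 and 0.558), against 0.5001, 0.4997 and 0.50004 in the simulations. The covariances were 2.65, 2.53 and 3.70, against simulated values of 0.0689, 0.0690 and 0.0688. Within the slides r was 0.588, 0.580 and 0.531 for the first pair, 0.616, 0.631 and 0.536 for the next, and 0.631, 0.623 and 0.580 for the last. The 3 seedling arrays were too few to split into sets of at least 2, and part of the excess in shared genes and in r may come from the shared seedlings. Shared arrays add equal covariance with or without changes, and the covariances exceeded the simulated ones by 2.58, 2.46 and 3.64. With normexp 338 genes were higher and 955 lower in every callus, and with median scaling 2979 and 1607.

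Direct comparison of 35S:WIND1 with T87 callus showed differences both ways. The meristem gene STM was 1513-fold higher (1 of 3 T87 arrays measured it) and CLV3 87.3-fold higher in 35S:WIND1 callus. Among genes with a symbol measured on every array of both groups, the largest differences upward were in the lipid transfer gene LTP2 (AT2G38530), by 756-fold (SE 0.91, adjusted p = 1.26e-05), and the dehydration-responsive RD22 by 605-fold (SE 0.73). Lower in 35S:WIND1 callus were NRT2.6 by 165-fold (SE 1.19, adjusted p = 0.000428), TIF3C2 by 114-fold and PAB5 by 101-fold. The embryo regulators LEC1 and FUS3 were lower by 104-fold (SE 0.35, adjusted p = 2.71e-07) and 84.1-fold.

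Xylem and secondary wall markers were higher in 14 of 15 cases (median 4.64, or 4.09 at bounds, adjusted p = 0.000426), with 6.73, 4.07 and 2.84 on the slides. XCP2 and XCP1 were 129.7-fold and 85.0-fold higher, and the list had adjusted p = 0.55 with an estimated correlation. Epidermis markers, among them LTP2, were higher in 11 of 12 (median 5.53, or 5.23 at bounds, adjusted p = 3.48e-06, or adjusted p = 0.432 with an estimated correlation). Phloem markers were higher in 4 of 6 (median 4.65, or 4.36 at bounds, adjusted p = 0.00878, or adjusted p = 0.478 with an estimated correlation), PP2-A1 by at least 129-fold and SUC2 by 51.6-fold. Root markers were higher in 12 of 18 (median 1.91, adjusted p = 0.00052), PYK10 by 141-fold, with adjusted p = 0.432 with an estimated correlation. Leaf polarity and meristem markers had 7 higher and 2 lower of 13 (median 2.24, or 2.104 at bounds, adjusted p = 0.0355, or adjusted p = 0.45 with an estimated correlation), KAN1 up at least 18.3-fold. This list did not pass without 35S:WIND1 replicate 1 (2.38, adjusted p = 0.0506) or 3 (2.19, adjusted p = 0.0541). Glucosinolate genes were higher in 15 of 16 (median 5.38, or 4.33 at bounds, adjusted p = 2.66e-06, or adjusted p = 0.392 with an estimated correlation). Flavonoid genes were higher in 9 of 15 (median 3.32, adjusted p = 0.0378, or adjusted p = 0.638 with an estimated correlation), but did not pass without 35S:WIND1 replicate 2 (2.88, adjusted p = 0.0582) or 3 (2.90, adjusted p = 0.0805). Jasmonate and wounding had 12 higher and 1 lower of 23 (median 2.06, or 1.31 at bounds, adjusted p = 0.00084), the lipoxygenase gene LOX2 up 20.5-fold, with adjusted p = 0.432 with an estimated correlation. Defence genes were higher in 9 of 16 (median 2.64, or 2.395 at bounds, adjusted p = 0.00251, or adjusted p = 0.499 with an estimated correlation), the salicylate exporter gene EDS5 by 27.9-fold.

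DNA replication was lower in 35S:WIND1 callus for 16 of 17 genes (median -2.40, adjusted p = 4.04e-07), with -1.79, -2.50 and -2.87 on the slides. MCM4 was 23.1-fold lower, and the list had adjusted p = 0.478 with an estimated correlation. Mitosis was lower for 14 of 24 (median -1.22, adjusted p = 0.000858, and -0.80 without 35S:WIND1 replicate 3), CDKB1;1 by 4.12-fold, with adjusted p = 0.655 with an estimated correlation. Of 19 ribosome genes 2 were lower (median -0.46, adjusted p = 0.00924, or adjusted p = 0.66 with an estimated correlation), RPS6B by 2.99-fold. This median was -0.27 without 35S:WIND1 replicate 3 and 0.05 (adjusted p = 0.144) with the deposited series values. The seed programme had 3 higher and 8 lower of 13 (median -2.77, adjusted p = 0.0231, or adjusted p = 0.45 with an estimated correlation), the oleosin gene OLEO1 down at least 45.3-fold and RAB18 up 14.4-fold. It did not pass without seedling replicate 3 (-2.77, adjusted p = 0.0624). Heat shock genes were lower in 8 of 10 (median -3.80, adjusted p = 0.00052, or adjusted p = 0.46 with an estimated correlation), HSP21 by 77.5-fold.

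The remaining lists did not pass between these calli (adjusted p in parentheses). Photosynthesis had 4 higher and 9 lower of 51 (0.483), and chlorophyll synthesis 2 and 5 of 18 (0.159). D-type cyclins had 5 and 3 of 17 (0.615), and regeneration regulators 12 and 5 of 32 (0.285). Auxin response had 8 and 5 of 21 (0.467), and cytokinin response 1 and 8 of 16 (0.0965). Hypoxia had 0 and 6 of 12 (0.063). Senescence had 2 and 2 of 13 (0.78), the clock 1 and 1 of 13 (0.497) and housekeeping 1 and 0 of 12 (0.766). Polycomb and DNA methylation had 3 and 3 of 23 (0.38), ROS1 up at least 91.2-fold, and stomata 4 and 2 of 10 (0.409). In other settings, given with median and adjusted p, hypoxia passed with normexp (-0.97, 0.0151), the deposited values (-0.75, 0.00632), no filter on dim probes (-1.26, 0.041) and without seedling replicate 3 (-1.26, 0.0468) or 35S:WIND1 replicate 2 (-1.78, 0.00244). Cytokinin response passed with the deposited values (-0.65, 0.0124) and without T87 replicate 1 (-1.62, 0.0231), and chlorophyll synthesis with normexp (-0.22, 0.0345). Adjusted over the list alone, photosynthesis had 3 higher and 8 lower, chlorophyll synthesis 1 higher, and stomata 3, root 1 and xylem 1 lower, and the other counts were the same.

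With limma, 4274 genes were higher and 3586 lower in 35S:WIND1 than in T87 callus (7587 with no array overlap). With the slide as a block 4245 were higher and 3582 lower, and 7695 of 7816 called genes kept their direction on all 3 slides. Median scaling gave 3283 higher and 5962 lower and the deposited values 6508 and 2131. The seed list did not pass with the former (-3.21, adjusted p = 0.128) nor leaf polarity with the latter (2.75, adjusted p = 0.0619). With normexp 3687 genes were called and 40 of 125 named changes ended or turned. The seed (-0.85, adjusted p = 0.381), flavonoid (1.32, adjusted p = 0.277) and leaf polarity lists (0.96, adjusted p = 0.208) did not pass with normexp, the last also with bright local backgrounds replaced (1.68, adjusted p = 0.052).

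Between 35S:WIND1 and 2,4-D-induced callus, WUS and CLV3 were at least 119-fold and 231-fold higher, and PLT2 and PLT1 at least 218-fold and 122-fold lower in 35S:WIND1 callus. The tonoplast aquaporin gene TIP2;2 (AT4G17340) was 1875-fold higher (SE 0.50, adjusted p = 3.21e-07), and the dehydration-responsive RD20 365-fold (SE 0.67). Lower in 35S:WIND1 callus were ARD3 by 498-fold (SE 0.91, adjusted p = 3.37e-05), CKX3 by 335-fold, the proton pump gene HA4 by 254-fold and GH3.2 by 225-fold (SE 0.35, adjusted p = 2.88e-07).

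Auxin response had 2 higher and 17 lower of 21 (median -3.002, adjusted p = 4.42e-06), with -2.82, -2.68 and -3.78 on the slides. IAA17 and IAA5 were 148-fold and 95.8-fold lower, and the list had adjusted p = 0.292 with an estimated correlation. Cytokinin response had 2 higher and 10 lower of 16 (median -2.79, adjusted p = 0.0013), ARR6 down 34.6-fold, with adjusted p = 0.499 with an estimated correlation. Hypoxia had 0 higher and 10 lower of 12 (median -2.44, adjusted p = 0.00207), with -3.59, -1.02 and -2.66 on the slides. PDC1 was 25.4-fold lower, and this list too had adjusted p = 0.499 with an estimated correlation. Mitosis had 1 higher and 5 lower of 24 (median -0.70, adjusted p = 0.0289, or adjusted p = 0.744 with an estimated correlation), the cyclin CYCA2;4 down 4.80-fold, with 0.25, -0.53 and -1.72 on the slides. It did not pass without 35S:WIND1 replicate 3 (-0.35, adjusted p = 0.225), without 2,4-D replicate 3 (-0.46, adjusted p = 0.119) or with median scaling (-1.01, adjusted p = 0.0795).

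All 51 photosynthesis genes were higher in 35S:WIND1 callus (median 3.299, adjusted p = 6.99e-22, or adjusted p = 0.45 with an estimated correlation), with 2.54, 2.93 and 4.39 on the slides. Of 18 chlorophyll genes 12 were higher (median 1.93, adjusted p = 3.93e-08), GLK2 by 39.1-fold, with adjusted p = 0.45 with an estimated correlation. Xylem markers were higher in 14 of 15 (median 4.65, or 4.55 at bounds, adjusted p = 2.39e-06, or adjusted p = 0.478 with an estimated correlation), with 6.85, 3.86 and 3.15 on the slides. Epidermis markers were higher in 7 of 12 (median 2.28, adjusted p = 0.00279, or adjusted p = 0.499 with an estimated correlation), the wax gene CER1 by 16.5-fold and ATML1, an epidermal identity factor, by 6.63-fold. Jasmonate and wounding had 13 higher and 1 lower of 23 (median 1.75, or 1.44 at bounds, adjusted p = 9.69e-05), JAZ9 up 18.4-fold, with adjusted p = 0.35 with an estimated correlation. Glucosinolate had 11 and 1 of 16 (median 3.67, or 3.04 at bounds, adjusted p = 6.47e-05), CYP83A1 up at least 739-fold, with adjusted p = 0.432 with an estimated correlation. Flavonoid synthesis had 11 and 1 of 15 (median 3.08, or 2.87 at bounds, adjusted p = 0.00417), TT19 up at least 25.6-fold, with adjusted p = 0.519 with an estimated correlation. Heat shock genes were higher in 6 of 10 (median 1.58, adjusted p = 0.0255, or adjusted p = 0.55 with an estimated correlation). This median was 0.96 without 35S:WIND1 replicate 2, and the list did not pass without 2,4-D replicate 3 (1.41, adjusted p = 0.0586).

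Among lists that did not pass (adjusted p in parentheses), DNA replication had 0 higher and 1 lower of 17 (0.0919), D-type cyclins 4 and 1 of 17 (0.308), and the ribosome 0 and 0 of 19 (0.52). Regeneration regulators had 6 and 14 of 32 (0.137). The seed programme had 5 and 1 of 13 (0.0851), RAB18 up 71.3-fold. Defence had 4 and 5 of 16 (0.909), senescence 1 and 6 of 13 (0.339), and the clock 0 and 2 of 13 (0.394). Polycomb and DNA methylation had 1 and 0 of 23 (0.261), housekeeping 1 and 0 of 12 (0.538) and stomata 4 and 2 of 10 (0.135). Root had 7 and 3 of 18 (0.18), phloem 3 and 0 of 6 (0.15), and leaf polarity 4 and 0 of 13 (0.0631). Again with median and adjusted p, the seed programme passed with median scaling (1.61, 0.0185) and without seedling replicate 3 (1.93, 0.0368), 35S:WIND1 replicate 3 (2.92, 0.0399) or 2,4-D replicate 2 (2.28, 0.0489). Leaf polarity passed with median scaling (0.22, 0.032), no filter on dim probes (0.53, 0.0342) and without 35S:WIND1 replicate 1 (1.31, 0.0464) or 2,4-D replicate 3 (0.91, 0.038). DNA replication passed without 35S:WIND1 replicate 1 (-0.85, 0.00858) or 2,4-D replicate 1 (-0.76, 0.0262), phloem without 35S:WIND1 replicate 1 (2.50, 0.0446) and stomata with median scaling (0.94, 0.0333). With the deposited values regeneration (0.11, 0.000192) and senescence (-0.61, 0.0286) passed. Adjusted over the list alone, chlorophyll synthesis had 13 higher, D-type cyclins 4 higher and 0 lower, jasmonate 15 higher, senescence 7 lower, glucosinolate 12 higher and xylem 15 higher, and the other counts were the same.

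With limma, 3579 genes were higher and 2491 lower in 35S:WIND1 than in 2,4-D-induced callus (5819 with no array overlap). A slide block gave 3553 higher and 2468 lower, and 5934 of 6035 called genes kept their direction on all 3 slides. Median scaling gave 3004 higher and 4007 lower and the deposited values 6245 and 1321, with which heat shock did not pass (2.24, adjusted p = 0.0752). With normexp 2456 genes were called and 53 of 110 named changes ended or turned. Mitosis (-0.28, adjusted p = 0.103), heat shock (0.57, adjusted p = 0.133) and flavonoid synthesis (0.71, adjusted p = 0.146) did not pass with normexp.

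Between the calli kept on auxin, RBCS3B was 532-fold higher in T87 callus (SE 0.53, adjusted p = 4.18e-07) and GDCH 249-fold (SE 0.29). Lower in T87 callus were ARD3 by 1178-fold (SE 0.91, adjusted p = 6.82e-06), the glycine-rich protein gene GRP9 by 1005-fold (SE 0.61) and the protease inhibitor gene KTI1 by 389-fold. The heat shock genes HSP21 and HSP22.0 were 421-fold and 226-fold higher (2 of 3 2,4-D arrays measured each).

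Of 51 photosynthesis genes all 51 were higher in T87 callus (median 3.65, or 3.55 at bounds, adjusted p = 3.78e-16, or adjusted p = 0.478 with an estimated correlation), with 3.15, 3.05 and 4.39 on the slides. Of 18 chlorophyll genes 14 were higher (median 2.95, adjusted p = 8.1e-07), CRD1 by 20.2-fold, with adjusted p = 0.478 with an estimated correlation. DNA replication was higher in 14 of 17 (median 1.97, adjusted p = 1.21e-05), MCM4 by 22.2-fold, with adjusted p = 0.499 with an estimated correlation. The seed programme was higher in 12 of 13 (median 3.56, or 3.52 at bounds, adjusted p = 6.47e-05, or adjusted p = 0.292 with an estimated correlation), FUS3 by 118-fold (2 of 3 2,4-D arrays measured it). Heat shock was higher in 9 of 10 (median 5.57, adjusted p = 7.77e-05, or adjusted p = 0.432 with an estimated correlation). Auxin response had 1 higher and 16 lower of 21 (median -3.63, adjusted p = 6.51e-05), with -3.33, -3.31 and -3.44 on the slides. GH3.1 and IAA17 were 154-fold and 153-fold lower, and the list had adjusted p = 0.35 with an estimated correlation. Regeneration regulators had 5 higher and 20 lower of 32 (median -2.09, or -1.83 at bounds, adjusted p = 0.00456, or adjusted p = 0.292 with an estimated correlation). PLT2 and PLT1 were at least 215-fold and 120.0-fold lower and BBM 332-fold, while MYB118 was at least 34.8-fold and ESR1 13.4-fold higher. Defence had 3 higher and 9 lower of 16 (median -1.85, adjusted p = 0.032, or adjusted p = 0.603 with an estimated correlation), PAD4 and EDS5 down 67.9-fold and 62.7-fold and WRKY53 up 4.68-fold. Epidermis markers were lower in 9 of 12 (median -3.60, or -3.33 at bounds, adjusted p = 0.0013), LTP2 by 83.5-fold, with adjusted p = 0.478 with an estimated correlation. Root markers had 1 higher and 9 lower of 18 (median -1.47, or -1.04 at bounds, adjusted p = 0.0198), PYK10 down 159-fold, with adjusted p = 0.499 with an estimated correlation.

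Lists that did not pass (adjusted p in parentheses) included mitosis with 4 higher and 1 lower of 24 (0.14), and D-type cyclins with 6 and 5 of 17 (0.735). The ribosome had 2 and 0 of 19 (0.063). Cytokinin response had 4 and 9 of 16 (0.113), jasmonate 4 and 6 of 23 (0.721), and hypoxia 1 and 7 of 12 (0.261). Senescence had 1 and 7 of 13 (0.409), flavonoid synthesis 5 and 3 of 15 (0.538), and glucosinolate 0 and 5 of 16 (0.225). The clock had 0 and 3 of 13 (0.183), Polycomb and DNA methylation 2 and 3 of 23 (0.943), and housekeeping 0 and 0 of 12 (0.812). Stomata had 3 and 2 of 10 (0.735), xylem 4 and 0 of 15 (0.363), phloem 1 and 4 of 6 (0.103), and leaf polarity 3 and 5 of 13 (0.409). By median and adjusted p, the ribosome passed with the slide as a block (0.37, 0.05), normexp (0.41, 0.0274), bright local backgrounds replaced (0.40, 0.0416), median scaling (0.49, 0.0372) and no filter on dim probes (0.37, 0.0359). It also did without 2,4-D replicate 2 (0.44, 0.0487) or 3 (0.36, 0.0271). Cytokinin response passed with normexp (-1.31, 0.0476) and the deposited values (-1.27, 0.042), and phloem with the deposited values (-2.60, 0.042) and no filter on dim probes (-2.20, 0.0353). Adjusted over the list alone, jasmonate had 5 lower, stomata 1 lower and xylem 3 higher, and the other counts were the same.

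With limma, 4198 genes were higher and 4089 lower in T87 than in 2,4-D-induced callus (8202 with no array overlap). A slide block gave 4173 higher and 4073 lower, and 8205 of 8227 called genes kept their direction on all 3 slides. With normexp 4233 genes were called, 49 of 126 named changes ended or turned, and regeneration (-0.96, adjusted p = 0.107) and root markers (-0.63, adjusted p = 0.0809) did not pass. In 10 of the list tests of all comparisons, none of them past the threshold, the median, the mean and the test differed in sign.

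**Figure D5:**
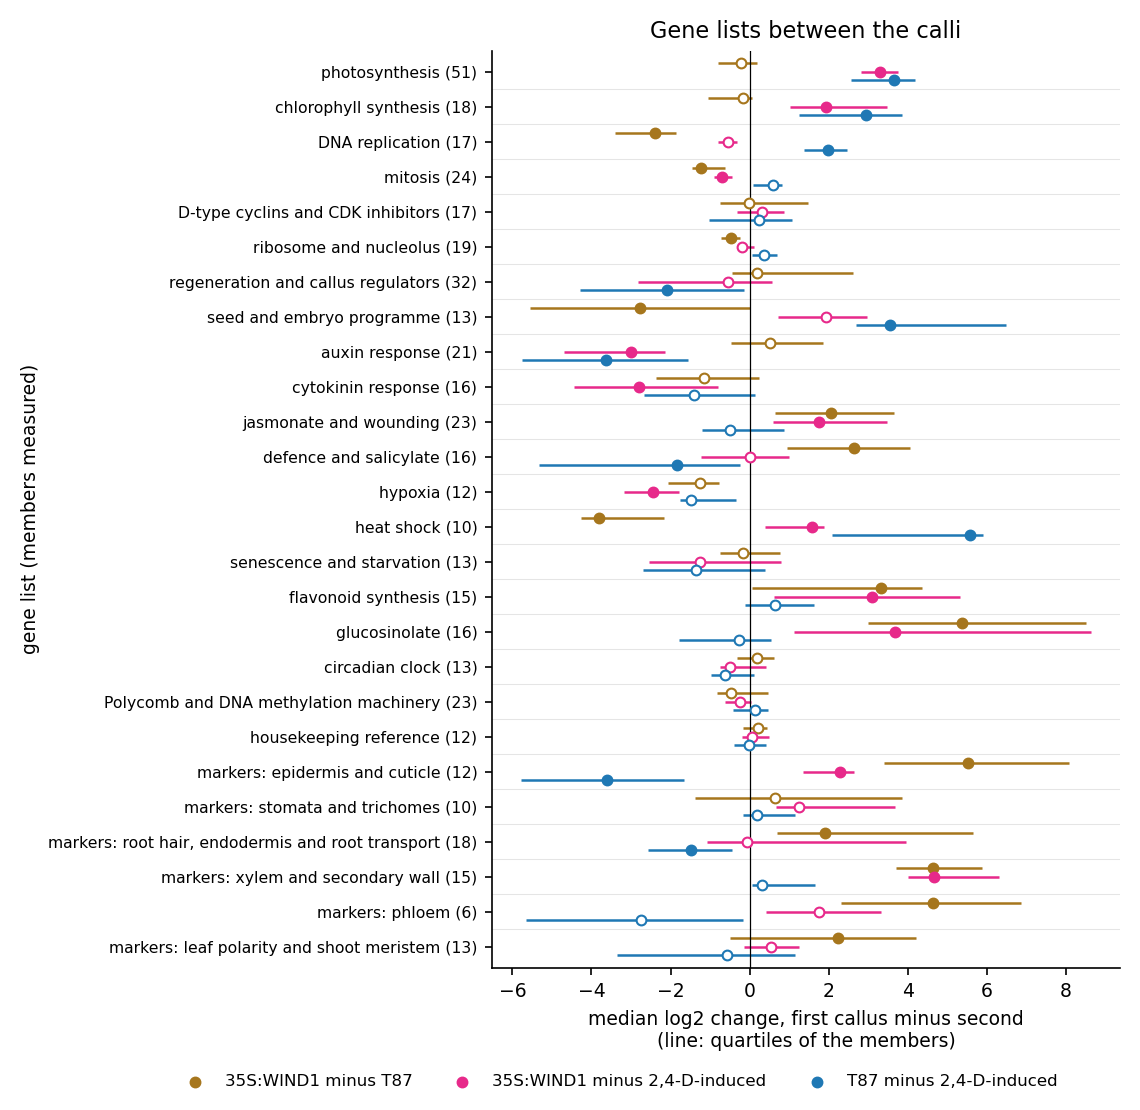
Median log2 change of each gene list (horizontal axis) between calli, where filled dots passed the list test with a preset correlation, open dots did not, and lines span the quartiles of the members. The xylem median is 4.64 for 35S:WIND1 over T87 callus and 4.65 for 35S:WIND1 over 2,4-D-induced callus, and the ribosome median of 35S:WIND1 over T87 callus, -0.46, turns to 0.05 with the deposited values.

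Some genes stood apart in a single callus, called in the same direction against each of the other 3 groups. In T87 callus these were 1680 higher and 1859 lower genes. FWA (AT4G25530) and SDC (AT2G17690), which DNA methylation keeps silent in most plant tissues, were higher by at least 1048-fold and by 1088-fold than in seedlings (1 seedling array measured SDC, 1 did not, and 1 spot was removed as an outlier). FWA was higher by at least 1274-fold and 1102-fold, and SDC by at least 1324-fold and 1146-fold, than in 35S:WIND1 and 2,4-D-induced callus. The cuticle gene BDG1 (AT1G64670) was lower by at least 116-fold than in seedlings, and by at least 77.0-fold and 65.9-fold than in those calli. In 35S:WIND1 callus 627 genes were higher and 274 lower, among them CLV3 and MCT1 (AT1G37140), the last higher by at least 118-fold than in seedlings and at least 141-fold than in T87 callus. SDR5 (AT2G47140) was lower by at least 10.4-fold than in seedlings, 12.2-fold than in T87 and 42.8-fold than in 2,4-D-induced callus, and QQS (AT3G30720), a gene linked to starch, by at least 9.01-fold, 126-fold and 326-fold. In 2,4-D-induced callus 1029 were higher and 1325 lower, with ARD3, CKX3 and GH3.2 among the former and RBCS3B, GDCH and ALDH11A3 among the latter.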

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

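The tests of left-over green or other seedling tissue and of scaling for the xylem markers, of dim probes for the spread of 35S:WIND1 callus and of scaling for FWA, SDC and ROS1 were chosen only after their results had been seen. The bounds of the other tests in this part were written before.

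Xylem and secondary wall markers lay near the seedling level in 35S:WIND1 callus (median log2 change 0.46) and far below it in T87 (-3.73) and 2,4-D-induced callus (-4.28). Green tissue alone is argued against by the 35S:WIND1 photosynthesis median (-2.65), but a share stays open. Scaling is argued against: the lowest 35S:WIND1 xylem median over T87 or 2,4-D-induced callus under other scalings and background corrections was 2.52. Other seedling tissue stays open: the root, epidermis and phloem medians of 35S:WIND1 callus were -0.48, -0.82 and -0.93, against -4.47, -7.12 and -5.56 in T87 callus, but their lower quartiles of -2.70, -2.36 and -2.64 show members far below the seedling level. The xylem markers varied between the 35S:WIND1 calli, with 2.31, -0.19 and -0.84 on the slides and replicate 1 above the mean of the others by 2.97. Xylem formation in 35S:WIND1 callus may be a biological difference, but genotype, medium and array position change together, so this stays open.

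The arrays of 35S:WIND1 callus were spread wider than those of the other groups, with replicate 3 nearest to the seedlings (array correlations across genes of 0.838 to 0.846, against 0.802 to 0.817 for the others). Dim probes or weak arrays are argued against: among the 10662 brightest genes the median SD was 0.259, which is 1.83 times the highest of the other groups (0.141). Different shares of seedling-like tissue between the replicates may contribute. In replicate 3 against the mean of the others, the lists meant to show it had medians of 0.294 for chlorophyll synthesis, 0.487 for photosynthesis and 2.16 for stomata and trichome markers. The lowest lay between the bounds of 0 and 0.3, so the test did not decide, and differences between single plants stay open as untested.

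FWA and SDC were far higher and ROS1 far lower in T87 callus than in any other group. Scaling is argued against, because the smallest of these log2 changes under the other scalings and background corrections was 2.72. Lower DNA methylation across the genome is a candidate explanation, under which loci that the reference calls pseudogenes would be higher in T87 callus. Of 3923 such loci 62, bright in some group, were measured. The medians of 62 such loci were 1.11 against seedlings (32 higher, 14 lower, adjusted p = 0.0546), 1.05 against 35S:WIND1 callus (31 and 10, adjusted p = 0.00408) and 0.289 against 2,4-D-induced callus (25 and 12, adjusted p = 0.189). Only the comparison with 35S:WIND1 callus passed, and it had adjusted p = 0.199 with an estimated correlation, so this stays open, as does the history of the cell line.

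For each count of called genes, 1 of the 10 splits of the 6 arrays, the real one, called as many genes, and with 3 arrays against 3 the share cannot be under 0.1. Against seedlings the real limma counts were 6844 for 35S:WIND1, 10110 for T87 and 9138 for 2,4-D-induced callus, and the highest other splits gave 1, 2 and 0. Between calli they were 7860 for 35S:WIND1 and T87, 6070 for 35S:WIND1 and 2,4-D-induced, and 8287 for T87 and 2,4-D-induced callus, and the highest other splits gave 1, 1 and 0.

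Against the seedlings the DNA replication list had 3 of 17 genes lower in 35S:WIND1 callus (median -0.62) and 14 higher in T87 callus (1.87), and the median difference between these calli was -2.40. The former lost its call with an estimated correlation (adjusted p = 0.698), with the deposited values (-0.13, adjusted p = 0.123) and without 35S:WIND1 replicate 3 (-0.38, adjusted p = 0.199), and the latter (adjusted p = 0.55) and the difference (adjusted p = 0.478) also did with an estimated correlation. Opposite calls against the seedlings, with the difference itself called, were found for 371 genes higher and 176 lower in 35S:WIND1 callus relative to T87 callus. The counts were 281 higher and 211 lower in 35S:WIND1 relative to 2,4-D-induced callus, and 241 higher and 473 lower in T87 relative to 2,4-D-induced callus. Among 2327 tested probes that are named by a genomic position and entered no comparison above, 263 were called higher and 377 lower in 35S:WIND1 callus than in seedlings, 436 and 557 in T87 callus, and 442 and 474 in 2,4-D-induced callus.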

How the results depend on the processing

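Normexp with bright local backgrounds replaced, the list tests under median scaling and the deposited values, and the list tests without single arrays were chosen after seeing the data. Called genes, shared and set-apart counts, correlations, WIND1 and list shifts made up 27 results. All were the same by the criteria used (direction and side of the threshold, counts within 1.5 times) with the mean of a gene's probes, only the 6 arrays compared, eBayes with trend and robust, and an adjusted p under 0.01, none of which was run for the list shifts. Replicate numbers did not pair the arrays: correlations of deviations ran from -0.136 to 0.124, with 2 of 18 above 0.1. The replicate block changed none of the 27 results, while 7 of 727 named changes lost their call under it and 1 list gained it. With an estimated correlation the 76 list calls became 0. Estimates above the preset 0.01 bear on this (0.828 for photosynthesis). With normexp the called genes were 2855, 5143 and 4670 for 35S:WIND1, T87 and 2,4-D-induced callus against seedlings. They were 3687 for 35S:WIND1 and T87, 2456 for 35S:WIND1 and 2,4-D-induced, and 4233 for T87 and 2,4-D-induced callus. Genes shared by all calli were 338 higher and 955 lower, and 251, 1267 and 1076 stood apart in 35S:WIND1, T87 and 2,4-D-induced callus. Bright local backgrounds on some arrays bear on this: the lower quartile of an array after normexp lay between 81.8 and 1839 units, against 78.2 to 98.6 with them replaced, and then all these counts came within 1.5 times of the reported ones. With normexp the mean correlation between single arrays was 0.726 for T87 callus and seedlings, 0.726 for 2,4-D-induced callus and seedlings, 0.799 for 35S:WIND1 and T87, 0.833 for 35S:WIND1 and 2,4-D-induced, and 0.801 for T87 and 2,4-D-induced callus. Called changes that turned under normexp were -0.0076 for HSP17.6II in 2,4-D-induced callus and -0.41 for JAZ8 and -0.32 for CLV3 in T87 callus against seedlings. Between T87 and 2,4-D-induced callus they were -0.26 for PAP1, -0.12 for CLV3, -0.11 for ARR16, -0.075 for MUTE, -0.20 for TT19 and -0.11 for CYCA2;1, and between 35S:WIND1 and 2,4-D-induced callus -0.018 for DML3 and -0.12 for SAUR15. With bright backgrounds replaced JAZ8 was at -0.021, and the correlations were 0.840, 0.726 and 0.740 of seedlings with 35S:WIND1, T87 and 2,4-D-induced callus, 0.816 and 0.844 of 35S:WIND1 with T87 and 2,4-D-induced callus, and 0.810 between the last. Without a filter on dim probes they were, in this order, 0.899, 0.806, 0.838, 0.868, 0.892 and 0.865; the cause was not tested. Of the 727 named changes, 256 lost their call with normexp and 11 turned, 45 and 1 with bright backgrounds replaced, 8 and 0 with quantile normalization, 20 and 0 with median scaling, and 41 and 0 with the deposited values. Lists lost and gained were 16 and 9 of 156 with normexp, 1 and 2 with backgrounds replaced, 0 and 0 with quantile normalization, 6 and 9 with median scaling, and 5 and 10 with the deposited values. Genes higher in all calli were 1454 with quantile normalization, and 2979, with 1607 lower, with median scaling. WIND1 in T87 callus against seedlings was 0.97 with quantile normalization and 0.98 with the deposited values, and in 35S:WIND1 over T87 callus 0.86 with median scaling and over 2,4-D-induced callus 1.37 with the deposited values; for these the cause was not tested. A filter on all 12 arrays tests fewer genes and left 4138, 6338 and 5975 calls against seedlings, and 4909, 3621 and 5507 between calli, in the order above. It left 1092 genes shared lower, and 501, 2017 and 1528 set apart. Under it fold changes correlated at 0.546 (35S:WIND1 and T87) and 0.566 (T87 and 2,4-D-induced), T87 arrays at 0.728 with seedlings and 0.754 with 2,4-D-induced callus. Without a fold minimum more genes pass by construction: 11452 and 14379 for 35S:WIND1 and 2,4-D-induced callus against seedlings, and 12746, 10578 and 13215 between calli. Then 2972 genes were shared higher, 1555, 6116 and 4576 stood apart, and WIND1 was called in 35S:WIND1 over 2,4-D-induced callus (0.71) and in T87 over 2,4-D-induced callus (-0.59). Without single arrays, WIND1 in T87 callus against seedlings ranged from 0.89 to 1.17 and lost its call in 4 cases: T87 replicate 1 (0.89) or 3 (0.96) and seedling replicate 1 (0.98) or 3 (0.99). Each such case has fewer arrays, and 16 to 24 named changes lost their call in each. Signal over background limits the rest: where a gene was not well above background in a group its fold change is only a bound, and the filter on all 12 arrays kept 341 of the 727 named changes, all 341 with their call.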

Other observations

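The tests of the tau class glutathione transferases and of the histones in this part had bounds written before their results were seen.

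Other genes with large changes were shared by the calli. FBA5, a fructose-bisphosphate aldolase gene, was lower than in seedlings by 5663-fold in 35S:WIND1 callus (1 of 3 arrays measured it), 2665-fold in T87 callus (1 of 3) and at least 2317-fold in 2,4-D-induced callus. DR4 was lower by 1385-fold and 2535-fold (2 of 3 arrays of each) and at least 2199-fold, and the auxin-responsive SAUR29 by at least 203-fold, 199.5-fold and 175-fold. Single calli stood apart in further genes. In T87 callus RGE1, a regulator of endosperm breakdown, was higher by at least 225-fold than in seedlings, 273-fold than in 35S:WIND1 and 237-fold than in 2,4-D-induced callus. In 2,4-D-induced callus the carboxypeptidase-like gene scpl14 was higher by at least 76.5-fold than in seedlings, 92.9-fold than in 35S:WIND1 and 91.5-fold than in T87 callus. BCAT7, a branched-chain aminotransferase gene, was higher there by 57.4-fold than in seedlings and at least 121-fold and 119-fold than in those calli. In 35S:WIND1 callus M17, a late embryogenesis abundant protein gene, was higher by 35.8-fold than in seedlings, 130.5-fold than in T87 callus (1 of 3 arrays measured it) and 46.3-fold than in 2,4-D-induced callus.

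As a hypothesis, 2,4-D in the medium may raise tau class glutathione transferase genes, which act on herbicides. Of 27 genes, 5 were higher and 8 lower in 2,4-D-induced than in 35S:WIND1 callus (median log2 change -0.049, quartiles -1.53 and 1.24, adjusted p = 0.731). Against seedlings 8 were higher and 12 lower (median -0.50, adjusted p = 0.594), and against T87 callus 12 and 4 (median 1.04, adjusted p = 0.126). No comparison passed. The median against 35S:WIND1 callus met the bound of 0 or lower that was set to exclude the hypothesis. By that bound the prediction failed for the list as a whole, though the median lay close to 0. Members went both ways, and single members may respond.

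A larger share of dividing cells in T87 callus was tested as a hypothesis on 18 histone genes. The lowest median was 0.139, against seedlings (3 higher, 0 lower, adjusted p = 0.368), followed by 0.164 against 2,4-D-induced callus (2 and 0, adjusted p = 0.461). Against 35S:WIND1 callus 7 were higher and 0 lower (median 0.936, adjusted p = 0.00329, or adjusted p = 0.554 with an estimated correlation). The hypothesis needed all of these comparisons to pass, and only the last did, while no median was 0 or lower, so the test did not decide.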
